A study of Mus musculus with 6 samples.

How the data were processed

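Messenger RNA was measured in 6 pools of mouse embryonic tissue, 3 wild-type and 3 Lmx1b-null, with 1 array per pool. Per the labels, every pool combined the hindlimb buds of 3 embryos of the 129Sv strain, 6 buds in all, taken at embryonic day 11.5. About 500 µm of tissue from the proximal part of each bud was used. Tissue was kept in a stabilising solution, RNA was extracted with Trizol and columns, its integrity was read on a Bioanalyser, and biotin-labelled cRNA was made with the array maker's protocol, per the labels' protocols. The authors deposited 1 value per probe set and array, made with RMA (robust multi-array average, which corrects background, normalizes between arrays and summarises the probes of a probe set), per the submitters' processing notes; its version is not given in the sources used here. The deposited values were taken as log2, since RMA returns log2 values and the values on each array ran from about 2 to 14; no label states the base of the logarithm. The lower quartile lay between 3.31 and 3.36, the median between 4.96 and 4.99 and the upper quartile between 7.05 and 7.10. Quantile normalization inside RMA gives arrays near-equal distributions, so a shift of most transcripts in 1 group would not be seen. RMA values near the bottom of the range carry little signal over background and compress fold changes there.

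Of 45101 probe sets, 64 control probe sets were left out and 45037 were tested. Gene names came from the platform annotation supplied with the data: 34945 tested probe sets had 1 gene symbol, 932 had several and 9160 were unnamed here. No gene was named from a probe set with several symbols. The gene identifiers of 34741 probe sets were found in a RefSeq table of assembly GRCm38.p6, and 0 symbols changed. That table also gave the chromosome of each gene and the order of neighbours; none of its coordinates are used, because no build is named for the arrays.

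The groups were compared with limma 3.58.1 in R 4.3.3. A linear model was fitted to each probe set with lmFit, and eBayes moderated its variance with no intensity trend and without the robust option. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. All changes are Lmx1b-null minus wild type on the log2 scale. A second fit used 1 probe set per gene, that with the highest mean over the 6 arrays, for 18193 genes. The labels name separate pools of embryos, so the 3 pools of a group were treated as biological replicates. With 3 pools against 3, an exact permutation test of 1 gene cannot go below 0.1, so limma's moderated p-values are reported. The median standard error was 0.0843 and the number of arrays limited the precision.

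The choices that follow were made before the data were examined. Gene lists, 27 in number, covered dorsoventral patterning, hindlimb identity and proximal factors, posterior Hox genes, apical ridge and Hedgehog signalling, the WNT, BMP and TGF-beta, and retinoic acid pathways, and chondrogenesis. Others covered tendon regulators, fibrillar collagens with small leucine-rich proteoglycans, limb muscle, axon guidance, LIM homeodomain factors, and genes that depend on LMX1B in other tissues. The rest covered chromosomal neighbours of Lmx1b, other cell types, the cell cycle, immediate early and heat shock genes, hypoxia with glycolysis, and sex-linked genes. The lists held 477 distinct genes, of which 445 were analysed here. Each list was tested with limma's camera, which asks whether its genes shifted relative to all other genes, at a preset inter-gene correlation of 0.01 and adjusted over the 27 lists. The same test with an estimated correlation and limma's fry were run beside it. Lmx1b itself was kept out of both. Counts of list members past the threshold were adjusted over all genes and over the list alone, with Lmx1b kept as a member.

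Genes to be named were fixed by rule. The rule took every probe set of Lmx1b, Wnt7a and En1, then up to 12 genes per direction with the largest change among those past the threshold whose pools did not overlap. It also took up to 4 members past the threshold from each list, or the member with the smallest p. Only 6 genes with an official symbol rose past the threshold, so 6 more with the smallest p were added and are said not to pass. The 45 distinct genes past the threshold over their list alone go beyond that rule, and naming them was chosen after their values were seen. So was naming the Nrp2 probe set not used for its list, Sema5a, Cadps2, Agtr2, and the list members given as examples that passed no threshold.

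The scripts were tested on data simulated from the 45037 probe sets of this comparison, with 200 of them changed, in 20 rounds. The fit recovered 43.4% of changes of 0.5, 93.8% of changes of 1 and 99.7% of changes of 2 or 3. The false share of calls was 4.6%, and a mean of 0.05 probe sets was called when nothing was changed. Only the probe set means were taken directly from the data. The noise was normal, independent between probe sets, and drawn with variances from limma's own fitted model. These rates thus check the scripts and do not give the error rate in the real pools. In independent simulated genes, a raised chondrogenesis list was called by camera in 20 of 20 rounds. Alternatives fixed beforehand were the pool number as a block, other variance models, array weights, repeated quantile normalization, median centring, and only probe sets above the median brightness. Leaving out probe sets with cross-hybridising suffixes, other thresholds, the mean of a gene's probe sets and leaving out each pool in turn were also fixed beforehand. An Xist covariate, leaving out chromosomes X and Y or 1 and 14, and leaving out wild-type pools 1 and 3 together were added after the data had been seen.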

Results

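The study asked which genes LMX1B controls as the mouse hindlimb forms. LMX1B is a LIM homeodomain transcription factor that specifies dorsal fate in limb mesenchyme. Expression was measured in the proximal hindlimb bud in 3 wild-type pools and 3 Lmx1b-null pools, each holding buds from 3 embryos. The arrays were alike in distribution, and correlations over all probe sets ran from 0.993 to 0.997 between arrays, within and between the groups. Group means are given as log2 RMA values with SD over n = 3 pools, and changes as null minus wild type with the standard error (SE) of the limma fit.

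The Lmx1b transcript itself fell 10.9-fold. Its brighter probe set read 8.02, 7.58 and 8.17 in wild-type pools 1 to 3 and 4.62, 4.23 and 4.57 in null pools 1 to 3. The means were 7.93 ± 0.31 and 4.47 ± 0.21 (SD, n = 3), a change of -3.45 (SE 0.16; limma adjusted p = 0.000544). The other Lmx1b probe set lay near the bottom of the range in both groups, at 3.93 and 3.92, with a change of -0.01 (adjusted p = 0.986). Which part of the gene either probe set reads was not known here, so the flat probe set checks nothing. Wnt7a, the dorsal ectodermal signal upstream of Lmx1b, changed by -0.04, 0.17 and 0.12 in its 3 probe sets, none past the threshold. En1, which marks ventral ectoderm, stood at 2.56 and 2.71 and did not pass either (adjusted p = 0.628).

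Of the probe sets past the threshold, more were lower than higher in null pools. Among the largest falls were those of Calb2, Kera and Cnmd. Calb2, which encodes the calcium-binding protein calretinin, fell from 8.31 ± 0.37 to 4.96 ± 0.28, or 10.2-fold (change -3.36, SE 0.20; limma adjusted p = 0.00168). Kera, the small leucine-rich proteoglycan keratocan, fell from 5.10 ± 0.33 to 3.25 ± 0.04, or 3.61-fold (SE 0.15; adjusted p = 0.00638), with the null mean near the bottom of the range, so the fold is inexact. Cnmd, the cartilage glycoprotein chondromodulin, fell from 6.74 ± 0.37 to 4.98 ± 0.31, or 3.38-fold (SE 0.21; adjusted p = 0.0395). Shox2, a homeobox gene needed for the proximal limb skeleton, fell in both of its probe sets, by 0.94 and 0.80 on the log2 scale (adjusted p = 0.00424 and 0.0238).

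In all, 38 of 45037 probe sets passed the threshold, 28 lower and 10 higher in null pools. Of these, 17 differed at least 2-fold. In all 38 the 3 null values lay outside the range of the 3 wild-type values. Chance alone gives this for 10% of unselected probe sets, but the threshold all but ensures it, so it adds no support. Of all tested probe sets, 9.41% had an unadjusted p under 0.05. The 38 included 25 distinct genes with 1 symbol. At 1 probe set per gene, 19 of 18193 genes passed, 16 lower and 3 higher. The counts rested on all 6 pools. Without null pool 1 the calls dropped to 13 probe sets and 4 genes, and without wild-type pool 2 to 15 and 7. Without wild-type pool 3 they were 21 and 7, without null pool 2 20 and 10, and without null pool 3 18 and 9, whereas 38 and 37 were called without wild-type pool 1, of which 20 and 17 were among the calls with all pools. With the Xist level in the fit, a setting chosen after seeing the data, 9 probe sets and 5 genes passed, 6 and 5 of them shared.

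Among the other falls were Syt13, a synaptotagmin family member (-1.06), Fam181b (-1.01), Aph1b, a gamma-secretase component (-0.97), and Gria2, an AMPA receptor subunit (-0.96). Agtr2, the angiotensin receptor type 2 gene, fell by 0.95 on the log2 scale at gene level (limma adjusted p = 0.0473). Cadps2, a regulator of dense-core vesicle release, changed by -0.88. Stk25, a serine/threonine kinase gene with 1 probe set, fell 3.44-fold (SE 0.15; adjusted p = 0.00869). The largest fall of all was in 1 probe set of Rpgrip1, which encodes a protein of the photoreceptor cilium, from 10.57 ± 0.48 to 5.95 ± 0.04 (change -4.62, SE 0.20). The other 3 Rpgrip1 probe sets stayed between 2.52 and 3.44, with changes from -0.04 to 0.22, and were too dim to show whether the gene fell. Dzip1 also had 1 probe set with a large fall, at -3.35, near the bottom of the range in null pools (3.03). Its 4 remaining ones changed by -0.05 to 0.10, among them a bright one at 7.84 in wild-type and 7.80 in null pools.

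Only 6 genes with an official symbol rose. Wdfy1, whose product binds endosomal phosphoinositides, rose 2.30-fold (change 1.20, SE 0.07; limma adjusted p = 0.00168), and 3 of its probe sets passed. The transcription factor gene Ebf2 rose 2.03-fold (SE 0.08; adjusted p = 0.00612), and 2 of its probe sets passed. Mapk8, the kinase JNK1, changed by 0.75 in 1 probe set, but its other 4 probe sets changed by -0.17 to 0.04. Kansl1l changed by 0.71 in 1 probe set, with values from -0.38 to 0.41 in the rest. Angptl1 changed by 0.62 in 1 probe set and by 0.16 and 0.60 in the remaining ones, which did not pass. Prr36 changed by 0.53. The next 6, Pou3f1, Pik3ap1, Supt16, Enox1, Mefv and Ap1s3, had adjusted p from 0.0553 to 0.0979 and did not pass.

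**Figure D1:**
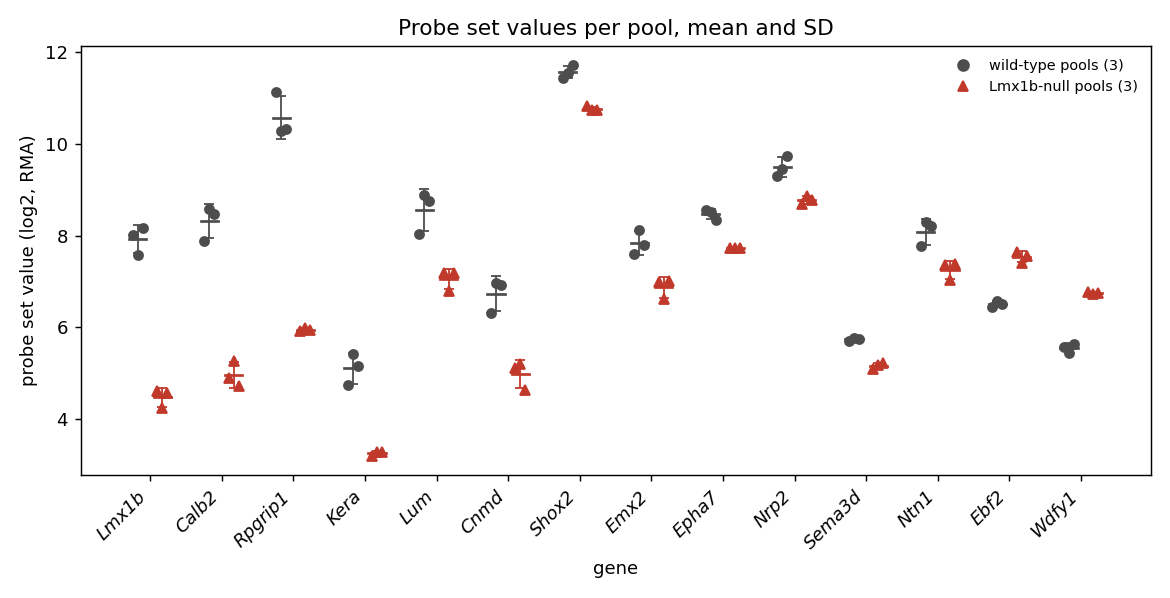
Log2 RMA values of 14 genes, 1 probe set each, in the 3 wild-type pools (grey circles) and the 3 Lmx1b-null pools (red triangles), with group means as horizontal bars and SD as error bars. The null pools lie below the wild-type pools for 12 genes, including Lmx1b, Calb2 and Kera, and above them for Ebf2 and Wdfy1; Lum, Emx2 and Ntn1 and the Nrp2 probe set shown did not pass the threshold over all probe sets.

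Genes for axon guidance ligands and receptors, the cues that steer motor axons in the limb, changed in both directions. Of 41 measured members, 2 fell when adjusted over all genes, Epha7 and Sema3d. When adjusted over the list alone, 8 fell, 2 rose and 31 did not pass. Epha7 fell from 8.47 ± 0.11 to 7.72 ± 0.00 (change -0.75, SE 0.07; gene-level limma adjusted p = 0.0145). Sema3d, a secreted semaphorin, fell by 0.58 on the log2 scale (gene-level adjusted p = 0.0283), while its dimmer probe set was at -0.04. Nrp2, a receptor for class 3 semaphorins, changed by -0.72 in the probe set used here, and by -0.87 in the probe set that passed over all probe sets (adjusted p = 0.024). The netrin gene Ntn1 (-0.84), the ephrin receptor gene Epha4 (-0.53) and its ligand gene Efnb2 (-0.42) fell over the list alone, with Slit2 (-0.35) and Gdnf (-0.34). Cxcl12 (0.30) and Ret, the GDNF receptor gene (0.33, at 3.82 and 4.15 near the bottom of the range), rose over the list alone. Over all genes neither rise passed (gene-level limma adjusted p = 0.202 and 0.381). Sema5a, a semaphorin gene outside the list, fell by 0.51 on the log2 scale (adjusted p = 0.0435).

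Because the changes went both ways, the list's median was 0.02 while its mean was -0.08 and camera's direction was down (adjusted p = 0.0622, not past the threshold). Over the alternatives that p ranged from 0.00467 to 0.726, with 7 of 18 past the threshold, among them those without wild-type pool 1 (0.00467) and without null pool 3 (0.0423). In either direction, fry gave an adjusted p of 1.19e-06 for the list. Fry does not compare a list with the other genes, and it called 14 of the 27 lists in this way.

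**Figure D2:**
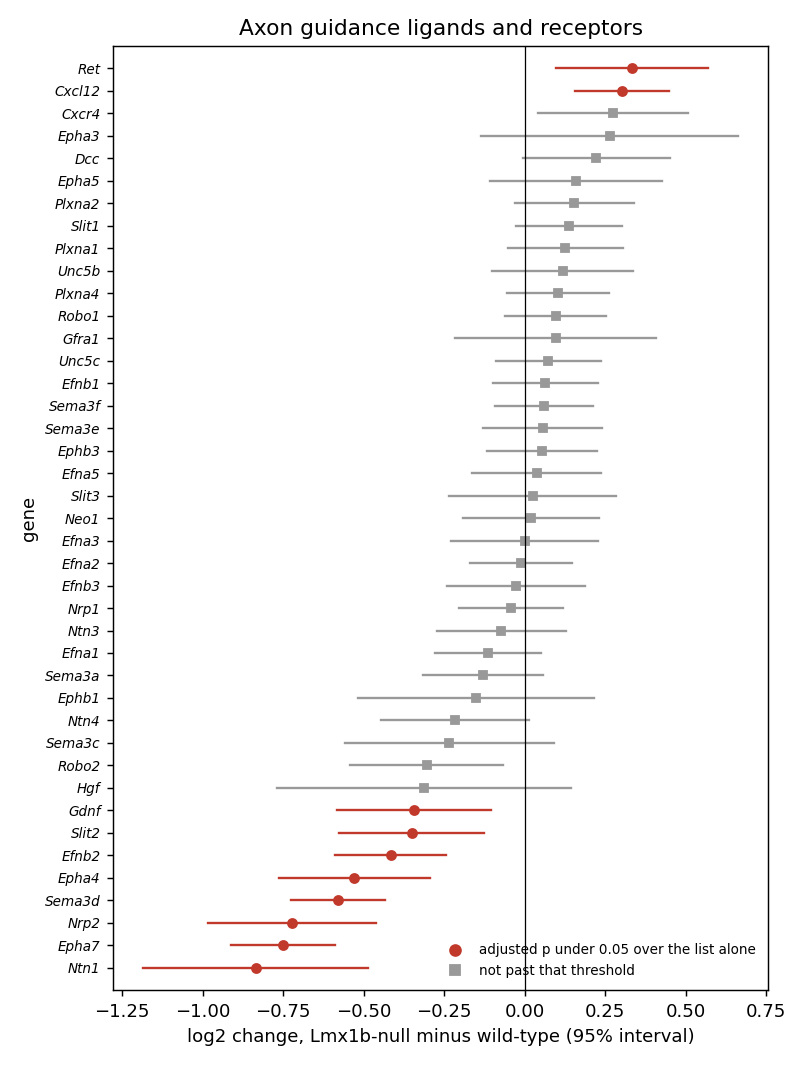
Log2 change, Lmx1b-null minus wild type, of the 41 measured axon guidance ligands and receptors, with 95% intervals from the limma fit (n = 3 pools per group). Red circles mark the 10 genes past the threshold over the list alone, from Ntn1 at -0.84 to Ret at 0.33; grey squares mark the 31 that did not pass.

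The list of transcription factors of hindlimb identity and the proximal limb was called lower (camera adjusted p = 0.0278; adjusted p = 0.628 with an estimated correlation), but 9 of its 22 members were higher and 13 lower. Its median was -0.02 against a mean of -0.10, or -0.07 without null pool 2. Of the members, Shox2 fell over all genes, and Emx2 (-0.97) and Tbx18 (-0.40), a pair of transcription factor genes of proximal mesenchyme, fell over the list alone; 19 did not pass. Tbx4 and Pitx1, the hindlimb selector genes, had changes of -0.29 and -0.15. The call was lost without null pool 2 (adjusted p = 0.288), among bright probe sets (0.122), without chromosomes 1 and 14 (0.0521), with the Xist level in the fit (0.0826) and with wild-type pool 2 alone (0.101); over all alternatives p ranged from 0.0117 to 0.628. The list of 14 posterior Hox genes, 10 of them higher, was not called (camera adjusted p = 0.229; 0.0482 without wild-type pool 3, range 0.0482 to 0.828), and the member with the smallest p, Hoxa10, was at 0.20.

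Chondrogenesis genes were lower, with 20 of 25 members below wild type (camera adjusted p = 7.86e-05; adjusted p = 0.726 with an estimated correlation). Cnmd fell over all genes. Hapln1, the cartilage link protein gene (-0.76), the joint growth factor gene Gdf5 (-0.88) and Sox5 (-0.29) fell over the list alone, and 21 members did not pass. Col2a1, the main cartilage collagen gene, was at 11.1 in wild-type pools with a change of 0.01, and Sox9 was at -0.19. Among alternatives with the preset correlation the p stayed at or below 0.027. The list score of wild-type pool 1, -0.13, lay with those of the null pools, at -0.13 to -0.07, while wild-type pools 2 and 3 stood at 0.23 and 0.22. The mean change of the list was -0.21, and -0.33 without wild-type pool 1.

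Among 22 fibrillar collagens and small leucine-rich proteoglycans, Kera fell over all genes. Lum (lumican, -1.50, SE 0.21) and Dcn (decorin, -0.79) fell over the list alone, and 19 did not pass. Col1a1 and Col3a1 had changes of 0.13 and 0.16. The list as a whole was not called (camera adjusted p = 0.723); its median of 0.12 was above 0, whereas its mean of -0.09 and the test pointed down. Without wild-type pool 1 it was called, lower (0.0132; range 0.00217 to 0.98). In the tendon and connective tissue list, Lox, the collagen cross-linking enzyme gene (-1.15), Osr2 (-0.49) and Mkx (-0.48) fell over the list alone. The tendon factor gene Scx (0.21) and Tbx3 (0.26) rose over the list alone, 13 of 18 did not pass, and the list was not called (0.668).

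Signalling lists were not called by camera in the fit of all 6 pools but held single changes. Grem1, a BMP antagonist gene, fell over all genes, from 6.44 ± 0.02 to 5.84 ± 0.06 (change -0.61, SE 0.06; limma adjusted p = 0.0238). In the BMP and TGF-beta list (camera adjusted p = 0.148; 0.000325 without wild-type pool 1, range 0.000325 to 0.965), Chrdl1 (-0.53), Gdf5 and Bmp4 (-0.28) fell over the list alone and Gdf10 (0.64) rose; 19 of 24 did not pass. In the apical ridge and Hedgehog list (0.3), Dlx5 (0.92), Fgf9 (0.45) and Hand2 (0.27) rose over the list alone. In the WNT list (0.294; called higher among bright probe sets at 0.0426, range 0.0426 to 0.864), Rspo1 (0.94), which encodes a WNT-enhancing R-spondin, was the only such member, and in the retinoic acid list (0.15) it was the receptor gene Rarb (-0.83). The dorsoventral list (0.644) held Lmx1b and Bmp4, with a median of 0.00 against a mean of -0.04 and a downward test. Its list-alone adjustment counted Lmx1b, the mutated gene, as a member, and Bmp4 passed in this list only for that reason.

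Muscle genes were higher in null pools, with 22 of 26 members of the limb muscle list above wild type (camera adjusted p = 0.000723; adjusted p = 0.726 with an estimated correlation). Msc, the myogenic repressor gene musculin (0.78), rose over the list alone; Myod1 (0.51) and Actc1 (0.65) did not pass. Wild-type pool 1 had the lowest list score, -0.41, and without it the mean change of the list was 0.09 instead of 0.23, with a p of 0.0311. Without wild-type pool 2 the mean change was 0.36. The p was 0.942 when wild-type pool 2 alone stood against the 3 null pools, and 0.858 with the direction turned when the Xist level was in the fit; over all alternatives it ranged from 3.26e-08 to 0.942.

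Endothelial genes were lower, with 19 of 20 members below wild type (camera adjusted p = 1.6e-05; adjusted p = 0.628 with an estimated correlation). Tek, the angiopoietin receptor gene, fell over the list alone (-0.65), and Kdr (-0.22) and Pecam1 (-0.19) did not pass. The mean change of the list was -0.16, and -0.10 without wild-type pool 3. The 13 hypoxia and glycolysis genes were all lower, none past the threshold, with Bnip3 at -0.66 and Ldha at -0.39 (camera adjusted p = 3.04e-05; adjusted p = 0.726 with an estimated correlation). That correlation was 0.964, and the list score of wild-type pool 3 was 0.76 against -0.25 to -0.05 in the other 5 pools. Without wild-type pool 3 the mean change of the hypoxia list was -0.06 instead of -0.35 and the adjusted p 0.122, and without wild-type pool 1 the mean change was -0.52; the p had a range of 1.76e-08 to 0.726 over the alternatives. With the Xist level in the fit the p was 0.129 for endothelium and 0.172 for hypoxia and glycolysis, and with wild-type pool 2 alone it was 0.0846 for endothelium, in a range of 3.26e-08 to 0.628.

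Spinal cord and somite genes were higher, with 10 of 12 members above wild type (camera adjusted p = 0.0143; adjusted p = 0.628 with an estimated correlation). The paired-box gene Pax9 (1.02) and the homeobox genes Meox1 (0.50) and Meox2 (0.25), all known from somites and also from limb mesenchyme or muscle precursors, rose over the list alone. Foxa2, a floor plate gene, also passed there (0.20), but at 3.10 and 3.30, near the bottom of the range. The neural genes Sox2 and Olig2 lay as low in wild-type pools, at 3.16 and 2.15, with changes of -0.10 and 0.02. The p was 0.0826 with the Xist level in the fit and 0.0751 with wild-type pool 2 alone, in a range of 0.000217 to 0.628.

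**Figure D3:**
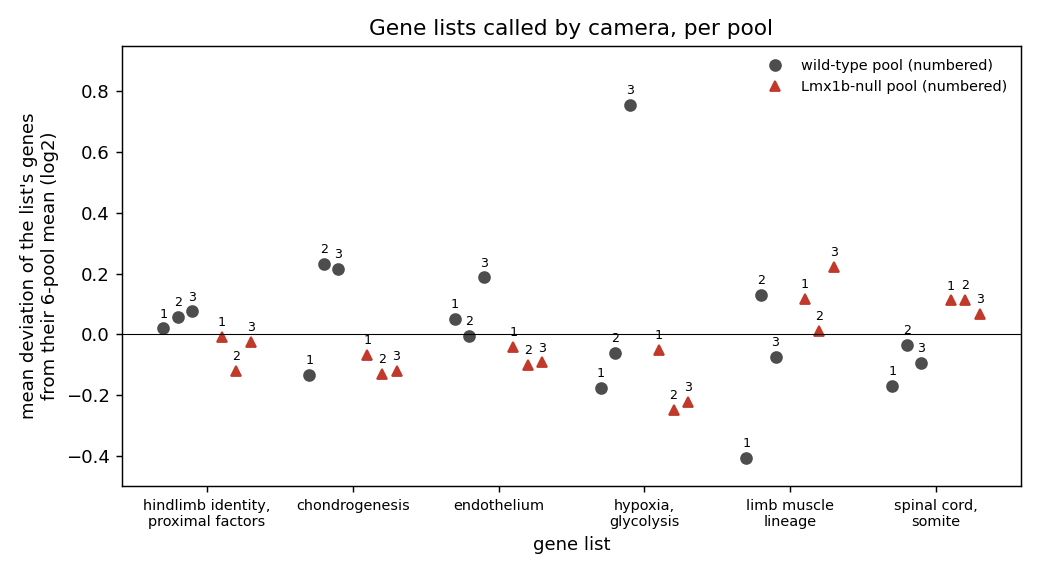
Mean deviation of each list's genes from their 6-pool mean (log2) in every pool, for the 6 lists called by camera; grey circles are wild-type pools and red triangles Lmx1b-null pools, numbered by pool. Wild-type pool 3 stands alone at 0.76 for hypoxia and glycolysis, wild-type pool 1 lies lowest for limb muscle at -0.41, and it lies with the null pools for chondrogenesis.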

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

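The alternatives on the Xist level, on chromosomes and on wild-type pool 2 alone were chosen after seeing the data; the cause of the differences was not tested unless stated. The counts depended on the variance model, the threshold and the pools. Against 38 probe sets and 19 genes, 94 and 36 were called with an intensity trend, 99 and 47 at an adjusted p under 0.1, and 17 and 9 with a 2-fold change required. Array weights called 69 probe sets, and bright probe sets alone gave 20. With the pool number as a block, 14 probe sets and 9 genes were called, 12 and 7 of them shared; same-numbered pools deviated with correlations of -0.239, -0.088 and -0.168, so the numbers share no more than a name, and the block changed no list call. Leaving out 1 pool gave 13 to 38 probe sets, 4 to 37 genes and 5 to 9 lists. With the Xist level in the fit, 9 probe sets, 5 genes and 3 lists were called, 6, 5 and 1 of them shared. Without chromosomes 1 and 14 it was 15 probe sets and 11 genes, and with wild-type pool 2 against the 3 null pools 10 and 11; that lone pool is assumed to vary like the null pools. Repeated quantile normalization, median centring, the robust option, removal of cross-hybridising probe sets and removal of X and Y kept the probe set count between 37 and 42 and the gene count between 16 and 20. The median change of all probe sets was 0.01 as deposited, 0.00 centred and 0.01 after repeated quantile normalization, and both scalings kept the 6 list calls and added ectoderm, higher, at 0.0428 centred and 0.0188 after quantile normalization.

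With an estimated correlation 0 lists were called, with adjusted p of 0.628 for hindlimb identity, endothelium and spinal cord with somite, and 0.726 for chondrogenesis, limb muscle and hypoxia. Hindlimb identity was lost among bright probe sets (0.122), with Xist (0.0826), without chromosomes 1 and 14 (0.0521) and with wild-type pool 2 alone (0.101), and ranged from 0.0117 to 0.288 with 1 pool left out. Hypoxia ranged from 1.76e-08 to 0.122 with 1 pool left out and was 0.172 with Xist. With Xist, limb muscle turned direction (0.858), and endothelium (0.129) and spinal cord with somite (0.0826) were lost; with wild-type pool 2 alone it was 0.942, 0.0846 and 0.0751 in that order. Of 378 values for lists not called, 20 had the other sign without a call and 26 were called. Reversals of single probe sets concerned only uncalled ones: the dim Lmx1b probe set was 0.018 with array weights, 0.089 with Xist, 0.061 with wild-type pool 2 alone and -0.059 to 0.054 with 1 pool left out, within -0.059 to 0.089 over all alternatives; the first Wnt7a probe set ran from -0.115 without wild-type pool 1 to 0.009 without wild-type pool 2, within -0.13 to 0.009 over all alternatives, and Xist was -0.012 with wild-type pool 2 alone. Camera was not run with the robust option. Detection calls were not used here, so changes of dim probe sets may be understated.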

Other observations

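The tests below on chromosome 1 and 14, on sex makeup and on single pools were chosen after the result was seen, except the test of the genes next to Lmx1b and the splits of the pools.

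Of the neuronal genes, 3 passed over the list alone, in both directions. Dcx, the doublecortin gene of migrating neurons (-1.87, SE 0.26), and Gap43, the growth cone protein gene (-0.57), fell, Gap43 also over all genes (gene-level limma adjusted p = 0.0491). Nefl, the neurofilament light chain gene, rose (0.96), and 15 of 18 members did not pass. Pan-neuronal Tubb3 and Stmn2 had changes of 0.13 and 0.04. The list was not called with all probe sets (camera adjusted p = 0.486) but was called lower among bright ones (0.0465; range 0.0465 to 0.828), with a median of 0.03 against a mean of -0.07 and a downward test. Of the LIM homeodomain factors and cofactors, Lmo1, a LIM-only cofactor gene, fell over the list alone (-0.86), and Lmx1b itself fell over all genes. The list was not called (camera adjusted p = 0.145, with 0.0369 without wild-type pool 2 and a range of 0.0369 to 0.798). Lhx2 and Lhx9, other LIM factors of the limb, had changes of -0.09 and -0.08.

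Markers of 5 other cell types did not pass as lists in the values as deposited. Camera's adjusted p was 0.296 for Schwann cells and neural crest, 0.0622 for ectoderm and epithelium, 0.486 for erythroid cells, 0.646 for macrophages and leukocytes, whose median (0.01) and mean (-0.01) differed in sign, and 0.35 for mesonephros, gonad and coelomic lining. No member of these 5 lists passed over its list alone. Ectoderm was called higher after repeated quantile normalization (0.0188), after median centring (0.0428) and among bright probe sets (0.00274). With 1 pool left out, it was called without wild-type pool 2 (0.00321), wild-type pool 3 (0.0482) or null pool 3 (0.00296), in a range of 0.00274 to 0.979. Schwann cells were called without wild-type pool 2 (0.00778; range to 0.932), erythroid cells without null pool 3 (0.00905; range to 0.833) and the cell cycle without wild-type pool 3 (0.00644; range to 0.765). It was 0.555 for genes that depend on LMX1B in other tissues, 0.0848 for the cell cycle, 0.486 for immediate early and heat shock genes, and 0.279 for the sex-linked list. The members with the smallest p were Ngfr (0.47), Epcam (0.22), Hbb-y (0.11), F13a1 (-0.20), Gata4 (0.21), Col4a3 (0.17), Top2a (-0.30), Fosb (0.23) and Xist (3.44), none past the threshold. In either direction, fry called 14 of the 27 lists, and in 1 direction it called 0, as did camera with an estimated correlation, where 6 were called at the preset one.

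The 38 calls came from the only split of the 6 pools that separated the genotypes. That was 1 of 10 splits of 3 against 3, and the highest count among the others was 0. So few splits cannot give a share under 0.05.

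The placement of the called genes over the chromosomes was examined. Of 25 distinct called genes, 5 were on chromosome 1 and 5 on chromosome 14, which together hold 9.42% of the genes placed. Of the 9 called probe sets that were higher and placed, 8 lay there. They are not independent, since they read only Mapk8, Kansl1l, Angptl1 and, with several probe sets each, Wdfy1 and Ebf2. In the first test, the gathering of genes did not exceed random placement. The densest run of 50 neighbouring genes held 4 genes at an unadjusted p under 0.001, on each of both chromosomes (permutation p = 0.209, one-sided). A second test was chosen after that one had missed. It counted 10 called genes on the 2 fullest chromosomes (permutation p = 0.0336, one-sided). After correction for the 3 placement tests tried this is 0.101, so random placement remains open. The other was Fisher's exact test on each of 20 chromosomes, on genes at an unadjusted p under 0.001 instead of called genes. In it, chromosome 1 had an adjusted p of 0.0451 and chromosome 14 of 0.0983, neither corrected for the 3 placement tests.

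The genes next to the mutated Lmx1b allele were not called (camera adjusted p = 0.836), but they lie on chromosome 2, so that test has no bearing on calls on chromosomes 1 and 14. Sequence variants between wild-type and null embryos, all of 1 strain per the labels, that alter single probe sets are a candidate explanation for part of the calls. On chromosomes 1 and 14, 4 of 10 called probe sets with a bright second probe set had none that moved the same way (Dzip1, Mapk8, Kansl1l and Angptl1), against 0 of 7 elsewhere; by gene, 3 of 7 against 6 of 6 had such a partner (Fisher's exact p = 0.0699, two-sided). An Angptl1 probe set that was higher by 0.60, at an unadjusted p under 0.05, was left out there as dim, though brighter than the called one; with partners at least as bright as the called probe set also counted, it was 3 of 10, and 4 of 7 genes against 6 of 6 (Fisher's exact p = 0.192, two-sided). This did not settle the matter, since Wdfy1, Ebf2 and Nrp2 moved in all of their bright probe sets. A response to the loss of LMX1B cannot be told apart from linked variants for the 13 called probe sets there, because the sequence of the pools there was not known here. These include probe sets of Rpgrip1, Cnmd, Ebf2, Stk25, Wdfy1 and Nrp2. The same holds for other named changes that were not called over all probe sets. Examples are Epha4, Msc, Ap1s3 and the Nrp2 list probe set on chromosome 1, and Rarb, Fgf9, Gdf10, Bmp4, Nefl, Supt16 and Enox1 on chromosome 14. Nor was the sequence of the pools known on the other chromosomes, so this limit is not particular to chromosomes 1 and 14. On chromosome 2, where Lmx1b lies, it covers the calls of Grem1 and Syt13 and the list-alone fall of Gdf5.

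The pools differed in sex makeup. Xist was at 4.68, 9.88 and 4.73 in wild-type pools 1 to 3 and at 9.66, 9.16 and 10.79 in null pools 1 to 3, and the Y-linked gene Eif2s3y was at 2.65 in null pool 3 against 5.86 to 7.12 in the other pools. For the called probe sets, a fit with the Xist level could hardly decide whether sex makeup was the whole cause of their changes. The threshold favoured probe sets with like values in the 3 wild-type pools, whose Xist levels differed. A probe set that followed Xist closely would thus rarely be called, and Xist itself did not pass (limma adjusted p = 0.468). With the Xist level in the fit, the change of the 38 probe sets had a median ratio of 1.042 to that without it (quartiles 0.953 and 1.113), all 38 kept their sign with an unadjusted p under 0.05, and 0 of the 29 that were placed lay on X or Y; at gene level, the called gene Agtr2 lies on X. With Xist in the fit 9 probe sets passed over all probe sets, 6 of them among the 38, with 3 residual degrees of freedom. The called changes thus did not follow the Xist level, a result largely set by how the probe sets were picked. Of the called gene lists, only chondrogenesis kept its call with Xist in the fit. Wild-type pool 2, the only wild-type pool with Xist near the null pools, had a chondrogenesis score of 0.233. Wild-type pool 1, at -0.134, lay with the null pools. The kept call thus leans largely on wild-type pool 2 and does not exclude sex makeup for that list. The camera adjusted p was 0.0826 for hindlimb identity and for spinal cord with somite, 0.129 for endothelium and 0.172 for hypoxia. It was 0.858, turned in direction, for limb muscle, so sex makeup stays open for these 5 lists. For hypoxia and glycolysis, wild-type pools 1 and 3 had like Xist levels (4.68 and 4.73) but list scores of -0.175 and 0.757. That list's score thus did not follow the Xist level in these pools, though this rests on wild-type pool 3.

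For 3 lists, single wild-type pools were weighed. Most of the fall of the hypoxia and glycolysis list came from wild-type pool 3. Without that pool the mean change was -0.06 instead of -0.35, and the camera adjusted p was 0.122 (range over the alternatives 1.76e-08 to 0.726). Much of the rise of the limb muscle list came from wild-type pool 1: without it the mean change was 0.09 instead of 0.23, though still past the threshold (0.0311). Against wild-type pool 2 alone it was lost (0.942), so differences among wild-type pools remain open. For axon guidance this stays open, since the 10 members that kept an unadjusted p under 0.05 without each pool had been chosen with the same pools. As a sign of RNA quality, the 3' minus 5' difference of the Gapdh control was 0.118, 0.082 and 0.081 in wild-type pools and 0.124, 0.146 and 0.191 in null pools, higher in every null pool, while that of actin overlapped (0.209 to 0.326 and 0.231 to 0.296). Whether this or the handling, dissection or stage of the pools bears on the changes was not tested.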
